A study of Mus musculus with 2 samples.

How the data were processed

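Small RNA libraries from 2 newborn mouse hearts were sequenced, 1 library per heart. Per the labels, both are hearts of B6NCrl pups at postnatal day 0, total RNA was the starting material and the size range was under 30 nt. The deposited tables hold read counts per gene, with no normalization, in whole numbers. Per the files that accompany the tables, the authors used build mm10 with GENCODE annotation M4 and made each table from 1 alignment file. The aligner, the counter and their versions are not given in the sources used here. How reads were trimmed is not given in the sources used here either.

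Each deposited table has 3 columns of counts without a header. The first column equals the sum of the other 2 in every gene row, so it was taken as the count on both strands. The second holds over 90% of gene counts and was taken as the count on the strand of the gene, and the third as the count on the opposite strand. This reading of the columns comes from the values. Unless stated otherwise, the sense-strand counts were used. The rows that name no gene were left out of totals and tests. Of all reads, 12.6% in replicate 1 and 15.5% in replicate 2 were unmapped, 35.9% and 34.6% matched several places, 1.93% and 2.28% fell in no gene on either strand, and 0 were ambiguous. Reads that matched several places are listed apart from the genes, so genes with repeated mature sequences can be undercounted. The gene totals used were 6373797 and 7630427. At this depth 3 counts are 0.471 and 0.393 CPM.

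Gene names, positions, introns and exons were taken from GENCODE M21 on the same build. 1894 of 1973 identifiers matched, and the 79 others had 0 counts together. A gene was marked as having repeated sequence when any 20 nt of its precursor occurred, on either strand, in another annotated microRNA precursor that it does not overlap, and of the 358 genes detected in both libraries 80 were. CPM, counts scaled to a library total of 1000000, was computed from the sense-strand total of each library. Values are the mean ± SD of 2 hearts.

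The lists, pairs and clusters, the tests on pairs, between hearts and on shared sequences, and most alternatives were fixed before the data were examined. The tests of the opposite-strand counts and of a few genes taking most counts were chosen after. There were 21 gene lists: cardiac muscle, skeletal muscle, endothelium, smooth muscle, mesenchyme and fibroblast, erythroid, leukocyte, neuronal, epithelial, hepatocyte, endocrine and sensory, pluripotent, the Dlk1-Dio3 imprinted cluster, other imprinted, Mir17 and paralog clusters, the Mir15, let-7, Mir29 and Mir30 families, Hox cluster and hypoxia. Of their 167 entries 155 were among the genes counted, and of 20 pairs 19 could be compared. Of 19 clusters 18 could be used. Named genes were the 20 with the highest mean CPM, the 2 most abundant of each list, the genes of the pairs, all members of the cardiac muscle list, and, of genes past the threshold between hearts with 100 or more counts, the 10 with the largest ratio each way.

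List shares carry exact Clopper-Pearson 95% intervals per library. Pair ratios were tested against 1 to 1 with 2-sided exact binomial tests. With 1 group there is no contrast for a test between conditions, so the 2 libraries were compared gene by gene with 2-sided exact binomial tests given the library totals, for genes with 10 or more counts together, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios used 0.5 added counts. List medians used log2(CPM + 1) and 10000 random lists, each member replaced by 1 of the 50 genes nearest in expression. Clusters with shared mature sequences were tested with an exact sign-flip permutation test. Spread was estimated with edgeR (common dispersion, intercept only, TMM factors).

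The test between hearts was tested on simulated data drawn from these genes and totals, with 431 genes tested. It called 83.7% of genes changed by 1.25-fold, 86.7% at 1.5-fold, 98.1% at 2-fold and 100% at 4-fold, and 0.433% of unchanged genes. The 200 changed genes were drawn only from genes with 100 or more counts in the 2 libraries together. The rates for changed genes therefore do not cover genes with fewer counts. The simulation holds sampling noise only. The alternatives were counts of both strands, each library alone, other scalings, other count minimums and pseudocounts, thinning to the smaller total, leaving out the most abundant gene, and a preset spread. Crediting the opposite-strand counts to the gene annotated there, and leaving out clusters whose neighbours share 20 nt with another gene, were added after the data were seen. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 (size factors only), Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.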

Results

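MicroRNA sequencing was carried out on whole hearts of newborn mice of the B6NCrl strain, a C57BL/6N substrain, at postnatal day 0. The libraries were made from total RNA and held molecules shorter than 30 nt. The labels give 1 group of 2 libraries. Replicate 1 came from the heart of pup 1 and replicate 2 from the heart of pup 3, so the replicates are separate animals. Each heart gave 1 library, so the spread between hearts includes any difference between library preparations. There is no second condition. The data therefore describe the microRNA population of the newborn heart, the ratios between related microRNAs, and how far 2 hearts differed. Replicate 1 had 6373797 counts on the strand of the microRNA genes and replicate 2 had 7630427. A gene with 0 counts could have been present at up to 0.471 CPM (counts scaled to the library total) in replicate 1 and 0.393 CPM in replicate 2, which is the level of 3 counts. Intervals and these floors cover counting error only.

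A small number of genes held most of the sense-strand counts. All ranks here are among the genes counted on that strand, and leave out reads that matched several places and reads on the opposite strand. The most abundant of these genes was Mir126a (ENSMUSG00000065540.1), an endothelial microRNA that lies within Egfl7, at 13.3% ± 1.55 of the counts (SD, n = 2). Mir208b (ENSMUSG00000077928.1), in an intron of the myosin heavy chain gene Myh7, followed at 10.5% ± 0.454. Mir143, a microRNA of smooth muscle, took 8.83% ± 0.449. Mir335, in an intron of the imprinted gene Mest, took 6.01% ± 0.205, and the X-linked Mir322 took 5.67% ± 0.0472. Next came Mir30e at 4.95% ± 0.578, Mirlet7i at 4.38% ± 0.171, Mir99a at 4.30% ± 0.716, Mirlet7g at 4.24% ± 0.0913 and Mir26b at 2.99% ± 0.0735.

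Together the 10 most abundant genes of each library took 65.2% ± 1.10 of the counts, and the 20 most abundant took 82.8% ± 0.419. The same 10 and the same 20 genes led both libraries. Ranks 11 to 20 by mean were Mir23a, Mir22, Mir130a, Mir21a, Mir30a, Mir23b, Mir30d, Mir351, Mir208a and Mirlet7d, the last at 1.09% ± 0.0967. Of the 20 genes, 8 lay in an intron, 6 overlapped an exon and 6 were intergenic on their strand. Mir23a and Mir23b share a stretch of 20 nt, so their counts are uncertain. In all, 358 of the 1973 genes had 10 or more counts in both libraries, 367 did in replicate 1 and 376 in replicate 2. With 1 count as the minimum the number in both was 574, and 1256 genes had 0 counts in both.

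**Figure D1:**
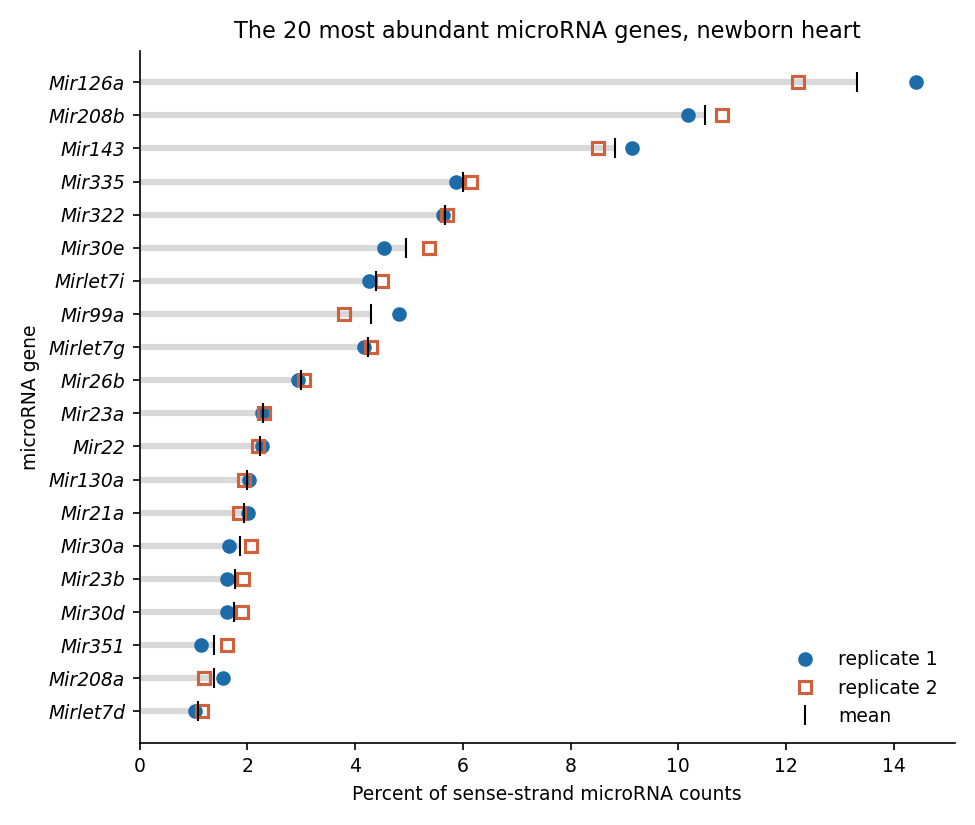
Share of sense-strand microRNA counts, in percent, of the 20 genes with the highest mean CPM. Circles are replicate 1, open squares replicate 2, and ticks with grey lines the mean of 2 hearts. Mir126a leads with a mean of 13.3% and Mirlet7d is last with 1.09%.

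Genes of the cardiac muscle list took 12.4% ± 0.193 of the counts (n = 2). The share was 12.2% in replicate 1 (exact Clopper-Pearson 95% interval 12.20 to 12.25) and 12.5% in replicate 2 (12.48 to 12.52). Nearly all of it came from microRNAs in introns of myosin heavy chain genes. Mir208b, in Myh7 on chromosome 14 (54975700 to 54975776, minus strand, mm10), had 104936 ± 4545 CPM. Mir208a, in Myh6 on chromosome 14 (54949060 to 54949142, minus strand), had 13703 ± 2426 CPM. Mir499, in Myh7b on chromosome 2 (155622880 to 155622958, plus strand), had 4977 ± 183 CPM. The other members counted were far lower, at 8.89 ± 1.63 CPM for Mir1a-1, 8.24 ± 1.88 for Mir133a-1 and 2.08 ± 0.163 for Mir133a-2. The sequences of these last 3 genes are repeated in other microRNA genes, so their counts are uncertain and the list share leaves out reads that matched several places. Mir1a-2, also in the list, is not among the genes counted, so the share leaves it out too.

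Within each heart the order of the myosin microRNAs was Mir208b, Mir208a, Mir499. Mir208b exceeded Mir208a by 6.60-fold in replicate 1 and 9.02-fold in replicate 2, a mean log2 ratio of Mir208a over Mir208b of -2.95 ± 0.32. Mir208b exceeded Mir499 by 19.9-fold and 22.3-fold, and Mir208a exceeded Mir499 by 3.02-fold and 2.47-fold. All of these ratios differed from 1 to 1 in both libraries. In the exact binomial tests of the 19 pairs of genes in 2 libraries, all 38 tests passed after Benjamini-Hochberg adjustment, with the highest adjusted p at 2.29e-06. A test within a library covers counting error only, and differences in capture between sequences are not removed.

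Vessel-associated microRNAs were also abundant. The endothelium list, Mir126a and Mir139, took 13.6% ± 1.53 of the counts, of which Mir139 gave 2865 ± 176 CPM. This share was 14.7% in replicate 1 and 12.5% in replicate 2, and without Mir126a it was 0.330%. The smooth muscle list, Mir143 and Mir145a, took 9.09% ± 0.450. These neighbours on chromosome 18 differed in level, with Mir143 above Mir145a by 34.8-fold in replicate 1 and 32.6-fold in replicate 2. The mesenchyme and fibroblast list took 2.10% ± 0.124, mostly from Mir21a at 19274 ± 1254 CPM. Mir214 had 1317 ± 24.4 CPM, and exceeded Mir199a-2, its neighbour in Dnm3os, by a mean of 33.5-fold. Mir199a-2 has repeated sequence, so that ratio is uncertain.

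Among microRNA families, let-7 took 10.8% ± 0.413 of the counts, led by Mirlet7i and Mirlet7g. The Mir30 family took 8.65% ± 1.06, with Mir30e above Mir30a by 2.73-fold in replicate 1 and 2.59-fold in replicate 2. The Mir15 family, linked to cell cycle exit of cardiomyocytes, took 6.54% ± 0.0561. Mir322 made up most of it, at 33.6-fold and 32.1-fold the counts of its neighbour Mir503, and Mir15a exceeded Mir15b by 4.20-fold and 4.15-fold. Mir17 and its paralog clusters, linked to proliferation, took 2.14% ± 0.167, led by Mir17 at 8690 ± 1134 CPM and Mir20a at 3762 ± 302 CPM, a ratio of 2.22 and 2.39. In the same list Mir106b exceeded Mir25 by 7.94-fold and 7.43-fold. The Mir29 family, regulators of collagen genes, took 0.0542% ± 0.00923, with Mir29a above Mir29c by 2.45-fold and 1.94-fold. Mir29c shares sequence with another gene. Repeated sequence was marked in 5 of 10 let-7 genes counted, 2 of 6 Mir30, 2 of 7 Mir15, 4 of 15 Mir17 list and 3 of 4 Mir29 genes. Mirlet7e, Mirlet7f-1 and Mir497 are not among the genes counted. The family shares and their leading genes are therefore uncertain.

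Imprinted microRNAs were widely detected. In the Dlk1-Dio3 cluster on chromosome 12, 38 of 40 genes counted had 10 or more counts in both libraries. The cluster took 1.53% ± 0.0137 of the counts, led by Mir411 at 3075 ± 165 CPM and Mir127 at 1717 ± 8.58 CPM. Mir411 shares sequence with Mir758. Of the list, Mir136, Mir299a, Mir376a, Mir376b, Mir380 and Mir409 are not among the genes counted, so the cluster share leaves them out. The list of other imprinted microRNAs took 0.601% ± 0.0600, led by Mir298 at 2352 ± 400 CPM and Mir483, near Igf2, at 1940 ± 187 CPM. Mir335, in an intron of the imprinted gene Mest and at 6.01% of the counts, is in neither list. Genes in Hox clusters took 0.201% ± 0.00754. Mir10b, in an intron of Hoxd3, exceeded Mir10a by 1.19-fold and 1.22-fold. The hypoxia-induced Mir210 took 0.105% ± 0.00726.

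Markers of blood and of other tissues took small shares. The erythroid list took 0.125% ± 0.0188, with 1084 ± 217 CPM for Mir451a, 91.5 ± 28.8 for Mir144 and 71.3 ± 0.0455 for Mir486. Mir451a exceeded Mir144, next to it on chromosome 11, by 8.32-fold in replicate 1 and 17.4-fold in replicate 2, and Mir126a exceeded Mir451a by 155-fold and 98.8-fold. The leukocyte list took 0.0655% ± 0.00344, led by Mir223 at 403 ± 9.21 CPM and Mir155 at 141 ± 39.6 CPM. Mir142, a main leukocyte microRNA, is not among the genes counted. With the opposite-strand counts at all 12 features that had 100 or more of them in each library credited to the genes annotated there, and added to the total, the share was 0.114% ± 0.00446, an alternative chosen after seeing the data. The epithelial list took 0.0313% ± 0.00183, led by Mir203 at 174 ± 3.22 CPM and Mir429 at 71.3 ± 13.2 CPM. The neuronal list took 0.0244% ± 0.00320, led by Mir128-1 and Mir138-2, both with repeated sequence. 4 of its 11 genes, Mir124a-1, Mir124a-2, Mir124a-3 and Mir9-2, had 0 counts in both libraries, but all 4 have repeated sequence. Of the 11 neuronal genes, 10 have repeated sequence, and Mir9-1 is not among the genes counted, so that share is uncertain.

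The pluripotent list took 0.0155% ± 0.000400, mostly from the Mir302 cluster on chromosome 3, with Mir302a at 60.4 ± 1.82 CPM and Mir302d at 50.9 ± 1.83 CPM. Mir302a shares sequence with Mir302b. The skeletal muscle list took 0.00933% ± 0.00235. Mir206, a skeletal muscle microRNA, had 87.4 ± 22.8 CPM, and exceeded Mir133b by 13.0-fold and 16.1-fold. Mir133b shares sequence with the Mir133a genes and is uncertain. The endocrine and sensory list took 0.00906% ± 0.000102, led by Mir7-1 and Mir182, with Mir182 above Mir183 by 2.01-fold and 3.03-fold. Mir7-1 shares sequence with Mir7-2. The hepatocyte microRNA Mir122 took 0.00402% ± 0.000621. Among the remaining pairs, Mir23a exceeded Mir23b by 1.40-fold and 1.20-fold, Mir27b exceeded Mir27a by 3.69-fold and 3.97-fold, and Mir221 exceeded Mir222 by 1.39-fold and 1.58-fold. Mir27a and Mir27b also share sequence.

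**Figure D2:**
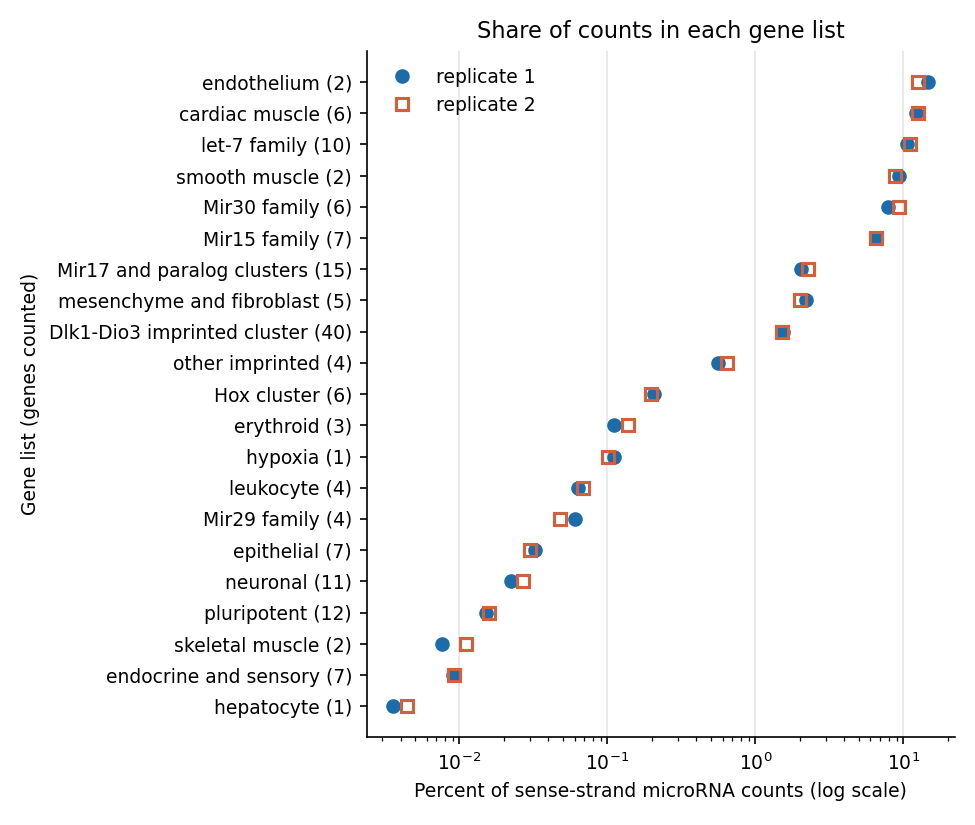
Share of sense-strand microRNA counts, in percent on a log axis, for each of 21 gene lists, with the number of genes counted in parentheses. Circles are replicate 1 and open squares replicate 2. The shares run from 0.00402% for the hepatocyte list to 13.6% for the endothelium list.

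Genes whose mature sequence has another copy in the genome were low beside neighbours that had been listed as unique. Over 18 clusters, the mean log2 difference was -4.10 ± 2.92 (SD), and the shared genes were lower in 17 of 18 clusters (exact sign-flip permutation test, 2-sided, p = 3.05e-05). The widest gaps were at Mir30c-1 beside Mir30e, with a log2 difference of -8.85, and Mir30c-2 beside Mir30a, with -8.16. Mir16-1 beside Mir15a differed by -0.82 and Mirlet7f-2 beside Mir98 by -0.61. The exception in direction was the pair Mir19b-2 and Mir92-2 beside Mir106a, Mir20b and Mir363, at 0.61. Mir23a and Mir27a beside Mir24-2, and Mir29c beside Mir29b-2, themselves share 20 nt with another gene. Without those 2 clusters, an alternative chosen after seeing the data, the mean was -4.04 ± 3.04, with the shared genes lower in 15 of 16 (exact sign-flip permutation test, 2-sided, p = 0.000122). Some clusters hold copies of the same mature sequence, such as Mir30c-1 and Mir30c-2. The clusters are therefore not independent, and both p-values can be too small. Reads that matched several places, which the tables list apart from the genes, were 35.9% of reads in replicate 1 and 34.6% in replicate 2.

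**Figure D3:**
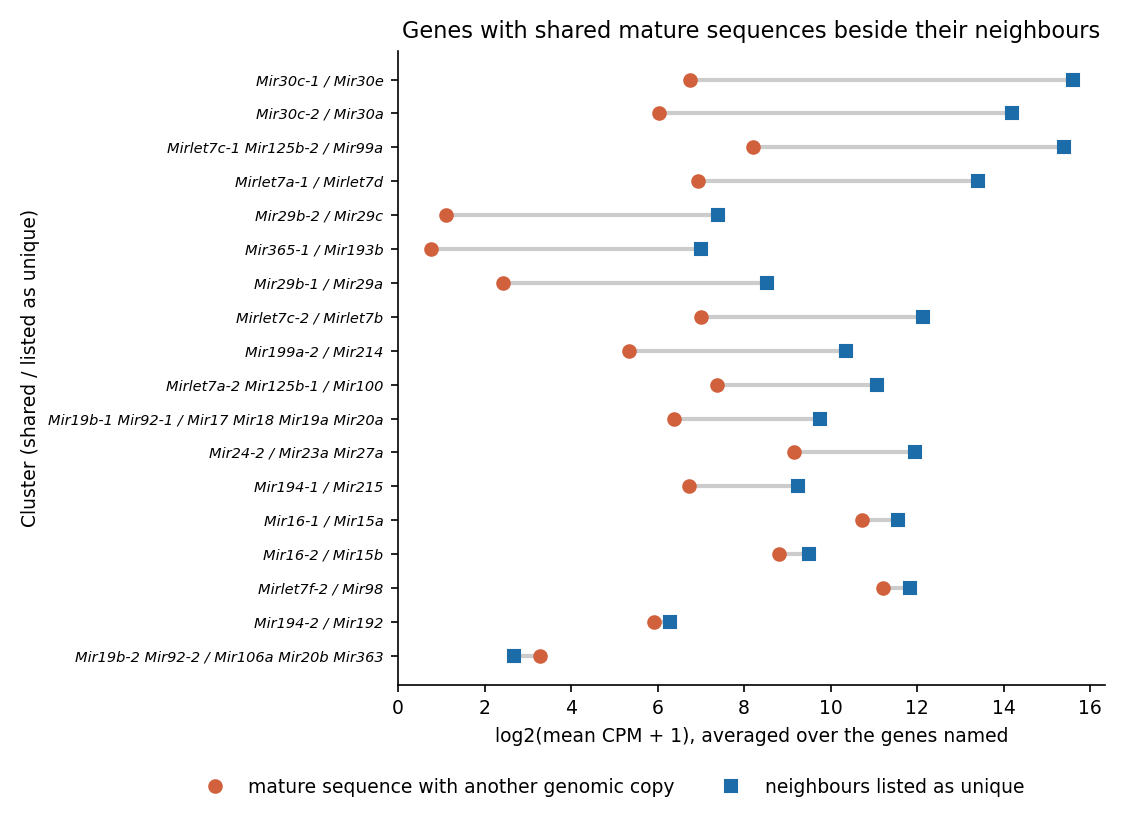
Mean abundance as log2(mean CPM + 1) of genes whose mature sequence has another genomic copy (circles) and of neighbours in the same cluster that were listed as unique (squares; Mir23a, Mir27a and Mir29c share 20 nt with another gene), for 18 clusters. The circle lies to the left of the square in 17 of 18 clusters, and the widest gap, -8.85, is that of Mir30c-1 and Mir30e.

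Most genes had small ratios between the 2 hearts, but many differed beyond sampling noise. Of 435 genes with 10 or more counts, 135 differed by the exact binomial test given the library totals (adjusted p under 0.05), 83 higher in replicate 2 and 52 higher in replicate 1. Most differences were small, with a median absolute log2 ratio of 0.24 among these genes, and 12 genes differed by more than 1.5-fold. With a minimum of 100 counts 135 of 275 genes differed, and all 20 of the most abundant genes passed. Genes with few counts that did not pass cannot be called alike. This test compares the 2 libraries, not conditions, and counts sampling noise only. With 1 library per heart, differences between the animals cannot be told apart from differences between library preparations. With the edgeR exact test at a preset biological coefficient of variation of 0.1, 1 gene passed, Mir181b-2 (29 at an unadjusted p under 0.05), and at 0.2 the edgeR exact test gave 0 genes (4 unadjusted). The spread estimated from these same 2 libraries was 0.114. A preset of 0.1 thus allows for about the spread it is set against, so the few calls say little about likeness.

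Among genes past the threshold with 100 or more counts, those with the largest ratios toward replicate 2 were Mir702 at 1.95-fold, Mir181b-2 at 1.92-fold, Mir362 at 1.72-fold, Mir770 at 1.69-fold, Mir7j at 1.54-fold, Mir877 at 1.52-fold, Mirlet7a-1 at 1.51-fold, Mir138-2 at 1.504-fold, Mir155 at 1.49-fold and Mir505 at 1.47-fold. Mir181b-2 had 358 CPM in replicate 1 and 687 in replicate 2 (exact binomial adjusted p = 6.01e-158), and shares sequence with Mir181b-1. Mirlet7a-1 and Mir138-2 also have repeated sequence. Among the same kind of genes, those with the largest ratios toward replicate 1 were Mir144 at 1.57-fold, Mir34b at 1.48-fold, Mir29a at 1.37-fold, Mir675 at 1.36-fold, Mir429 at 1.301-fold, Mir195a at 1.296-fold, Mir208a at 1.29-fold, Mir33 at 1.28-fold, Mir99a at 1.27-fold and Mir30b at 1.23-fold. Mir675 lies in an exon of H19 and Mir770 in an exon of Meg3, both maternally expressed imprinted genes. The only 2 genes past the threshold by more than 2-fold had few counts and were picked out after their values were seen. Mir1927 had 13 and 41 counts, and Mir7226 had 12 and 2.

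By list, 9 of 10 let-7 genes tested were higher in replicate 2 past the threshold, and 10 were when adjusted over the list alone. Mirlet7d was 1.13-fold higher and Mirlet7i 1.06-fold, and Mir98, at a log2 ratio of 0.03, was the gene that did not pass over all genes. With TMM factors or DESeq2 size factors Mirlet7b also fell short, which left 8. Of the 10 let-7 genes, 5 have repeated sequence, so their counts are uncertain. In the Mir30 family 4 genes were higher in replicate 2 and 1, Mir30b, in replicate 1, with 5 past the threshold when adjusted over the list alone. In the cardiac muscle list Mir208b was 1.06-fold higher in replicate 2, while Mir208a and Mir499 were 1.29-fold and 1.05-fold higher in replicate 1, and the other 3 did not pass. That was also 3 when adjusted over the list alone. In the erythroid list Mir451a was 1.33-fold higher in replicate 2 and Mir144 1.57-fold higher in replicate 1. In the Dlk1-Dio3 cluster 7 genes were higher in replicate 2, 5 in replicate 1 and 26 did not pass, with 13 past the threshold when adjusted over the list alone. With TMM or DESeq2 size factors Mir665 also fell short, which left 6 higher in replicate 2 and 27 that did not pass. All 7 endocrine and sensory genes and all 7 pluripotent genes tested stayed short of the threshold, and 0 passed when adjusted over the list alone.

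Set against 10000 random lists matched on expression, the let-7 list had a median log2 ratio of replicate 2 over replicate 1 of 0.21, at percentile 97.7, and the Mir30 family 0.24, at percentile 97.6. At the other end stood the Mir29 family at -0.22, percentile 4.34, and the cardiac muscle list at -0.09, percentile 7.59, whose share of counts was nonetheless higher in replicate 2 because of Mir208b. The Dlk1-Dio3 cluster had 0.02, at percentile 36.7. With a pseudocount of 10 CPM the Mir29 median was -0.09, at percentile 8.66, and 3 of the 4 Mir29 genes have repeated sequence. In the cardiac muscle list 3 of the 6 genes have repeated sequence, at 2.08 to 8.89 CPM. The cardiac median thus rests in part on genes with uncertain counts. The let-7 genes with repeated sequence had log2 ratios of 0.23 to 0.60 and the others 0.03 to 0.18. The let-7 median therefore rests largely on genes with uncertain counts. These percentiles describe the 2 libraries and are not tests. The other 11 of 16 lists lay between percentiles 13.0 and 90.8.

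**Figure D4:**
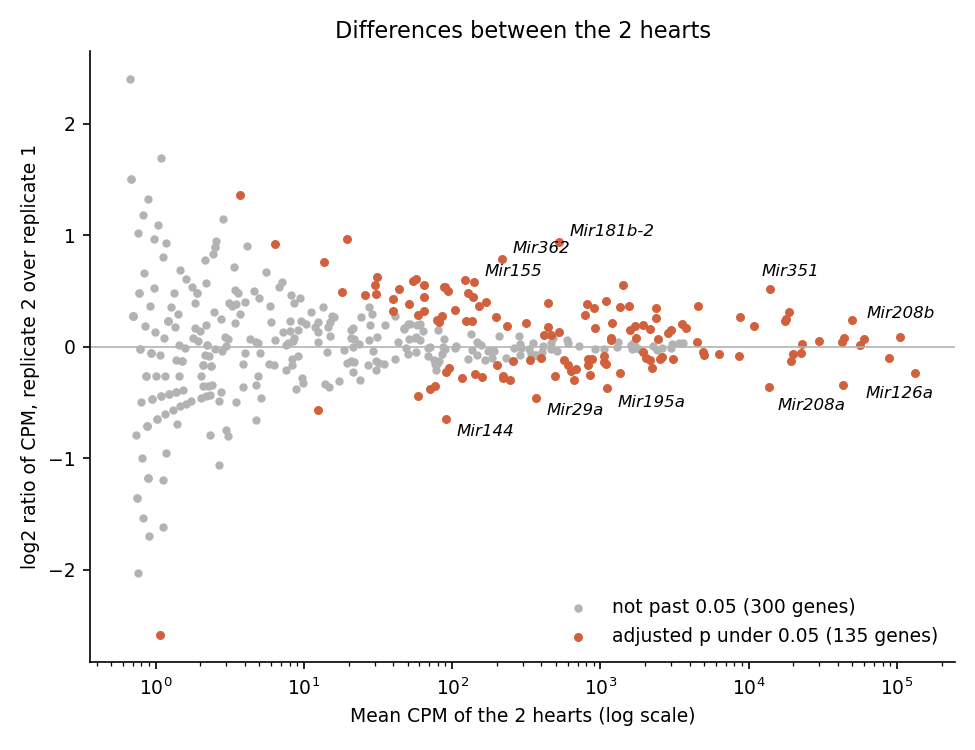
Log2 ratio of CPM, replicate 2 over replicate 1, against the mean CPM of the 2 hearts on a log axis, for 435 genes with 10 or more counts. Coloured points are the 135 genes with an adjusted p under 0.05 in the exact binomial test of the 2 libraries, and grey points are the rest. Ratios narrow as abundance rises, and the 20 most abundant genes lie between -0.36 and 0.52.

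Across genes the 2 hearts had a Pearson correlation of 0.997 and a Spearman correlation of 0.989 of log2(CPM + 1), where genes are not independent replicates. The median absolute log2 ratio was 0.19, and 0.09 with a pseudocount of 10 CPM. The common biological coefficient of variation from edgeR was 0.114. Against sampling noise, the chi-square per gene had a median of 1.93 and a mean of 131, and the 20 most abundant genes gave 81.9% of the sum.

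Counts on the strand opposite to the counted genes were 7.15% of gene counts in replicate 1 and 7.22% in replicate 2, and enter none of the values above except the leukocyte share with such counts credited. Of these, 86.5% in replicate 1 and 86.4% in replicate 2 fell at Gm25301 (ENSMUSG00000093026.1) on chromosome 18 (61397813 to 61397925, plus strand, mm10). Set among the sense counts of the other genes, they would rank 4 in both libraries. That feature had 1 count on its own strand in each library and 424423 and 513236 on the other. On the minus strand the GENCODE annotation places Mir378a there (61397835 to 61397900), in an intron of Ppargc1b, a coactivator gene of mitochondrial metabolism.

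**Figure D5:**
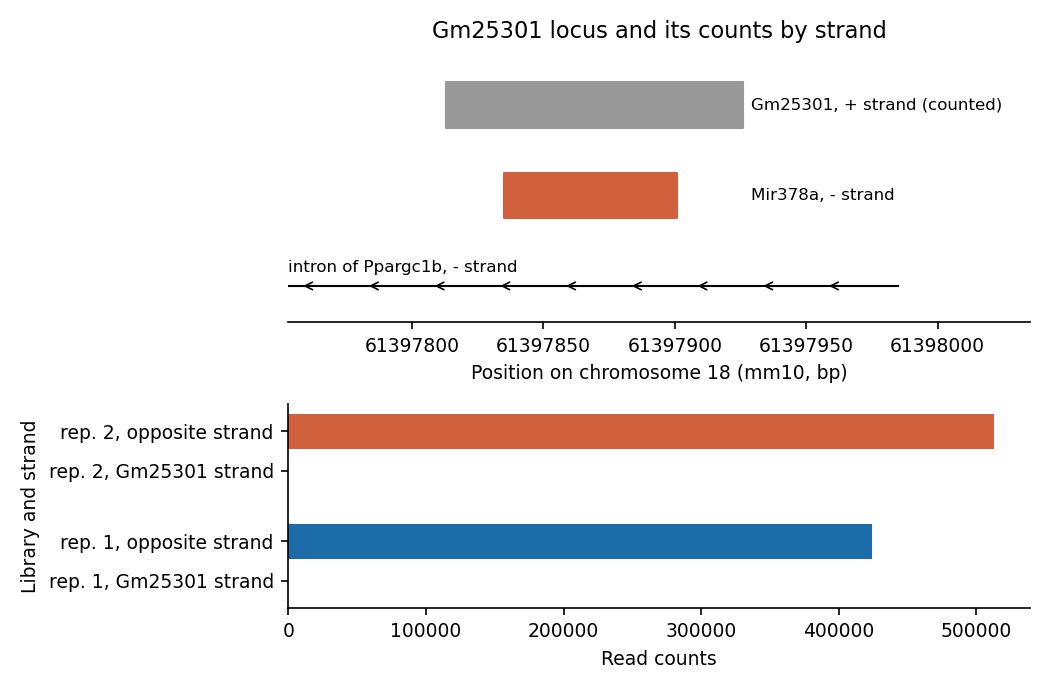
Map of the Gm25301 locus on chromosome 18 (mm10 position in bp) with the counted feature on the plus strand, Mir378a on the minus strand and the intron of Ppargc1b, above bars of read counts by library and strand. The bars on the strand opposite to Gm25301 reach 424423 and 513236, and those on its own strand are 1 each.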

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

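The tests of the opposite-strand counts and of a few genes taking most counts were chosen after the result was seen. The tests of paralog sharing and of GC content were written down first. The labels give 1 group, so no biological explanation of these patterns was tested.

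Counts on the opposite strand, which the comparisons do not use, stood far above the floor of 3 counts at 12 features with 100 or more such counts in each library. Over both libraries together they were 937659 at Gm25301, 56917 at Gm25927, 31794 at Gm24083, 11838 at Gm25252, 10775 at Gm24321, 10485 at Mir497b, 9159 at Mir299b, 8001 at Mir142b, 4198 at Gm25750, 2024 at Gm24111, 645 at Mir3074-1 and 564 at Mir1b. Together these features held 99.97% of opposite-strand counts in each library.

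Loss of strand in the libraries is argued against, because among 58 genes with 10000 or more sense counts in each library the highest opposite-strand share was 0.0541%, for Mirlet7b. A candidate explanation is reads of a microRNA gene on the other strand that is not among the genes counted. All 12 features lie over such a gene in GENCODE M21, against 20 of the 1882 others (Fisher's exact test, 2-sided, p = 5.26e-23). The overlapped genes, in the order above, are Mir378a, Mirlet7e, Mir191, Mir376a, Mir409, Mir497, Mir299a, Mir142, Mir380, Mirlet7f-1, Mir24-1 and Mir1a-2. If the counts belong to them, Mir378a would hold 6.21% ± 0.0406 of the gene counts of both strands.

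Reads that matched several places, also outside the comparisons, were 35.9033% of reads in replicate 1 and 34.6352% in replicate 2. Genes with another genomic copy of their mature sequence had fewer counts than neighbours listed as unique in 17 of 18 clusters, though some, such as Mirlet7f-2 with 13831 and 19783 counts and Mir16-1 with 10118 and 13784, were well covered. Reads shared between paralogs may account for it: the mean log2 difference of -4.10 is below the -1 set in advance (exact sign-flip permutation p = 3.05e-05). Clusters that hold copies of the same mature sequence are not independent, so that p-value can be too small. Levels that differ within a cluster for other reasons stay open. Of 11 pairs of neighbours listed as unique, 7 differed by 0.015 to 2.77, less in size than that mean, and 4 by more, 3 of them with Mir19a (up to 9.34) and the other Mir23a and Mir27a, which share sequence with other genes. Mir23b and Mir27b, the pair at 2.77, also share sequence with other genes. Many of the pairs have genes in common, so they are not independent. The pairs among Mir106a, Mir20b and Mir363 differed by 0.17, 0.19 and 0.015. These genes were all low, at 5.93, 5.14 and 5.08 CPM, so their small gaps say little.

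All 10 let-7 genes tested had higher CPM in the second heart, under total counts, TMM factors and DESeq2 size factors alike. GC content bias of the precursors is argued against: after the linear trend was removed the median log2 ratio was 0.20, from 0.21, with a slope of -0.01 ± 0.02 (bootstrap SD) per 10 percentage points. A few genes taking most of the counts is argued against for the list median of 0.21, because the median of all tested genes was 0.0242. That comparison cannot decide for the let-7 genes without repeated sequence. Of these, Mir98 (0.030), Mirlet7b (0.041) and Mirlet7g (0.044) lay near that median, below Mirlet7i (0.080) and Mirlet7d (0.18). The 5 let-7 genes with repeated sequence, whose counts are uncertain, had log2 ratios of 0.23 to 0.60, and the others 0.03 to 0.18. GC content of the mature sequences, reads that matched several places, library preparation, and a difference between the pups were not tested and remain open.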

How the results depend on the processing

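Of 277 values under alternatives, 225 stayed within the spread between hearts, or within 1.5 times for counts and spreads, or on their side of the threshold for tests, and 0 reversed. Of the 225, 86 leave out 1 library. For shares these say nothing about stability, since either value of a pair lies within the SD of their mean. The 19 pair ratios were tried only by leaving out 1 library and with counts of both strands, which hardly change these genes, so their stability was not tested. The cause of the other moves was not tested unless the construction shows it.

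Genes detected in both libraries went from 358 to 574 with a minimum of 1 count. Genes that differ between the hearts went from 135 (83 and 52) to 1 with the edgeR exact test at a preset spread of 0.1 (1 higher in the second heart, 0 in the first), with 29 at an unadjusted p under 0.05. At a preset of 0.2 the edgeR exact test gave 0 (0 and 0), with 4 unadjusted. By construction these presets allow for spread between hearts, and 0.1 is close to the 0.114 estimated from these same libraries. Other settings gave 127 to 146 genes. The median absolute log2 ratio went from 0.185 to 0.0945 with a pseudocount of 10 CPM, which by construction pulls low genes together, and the endocrine and sensory list median from 0.256 to 0.0519.

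By construction, shares move with the denominator and, where opposite-strand counts are credited, also with the members added to the lists, such as Mir142 to leukocyte and Mir299a, Mir376a, Mir380 and Mir409 to Dlk1-Dio3. With counts of both strands the 10 most abundant genes took 63.9%, cardiac muscle 11.5%, smooth muscle 8.43%, mesenchyme 1.95%, leukocyte 0.0608%, endocrine 0.00845%, pluripotent 0.0144%, Dlk1-Dio3 1.42%, Mir15 6.07%, let-7 10.02%, Hox 0.187% and hypoxia 0.0979%. With opposite-strand counts credited to the genes annotated there, an alternative chosen after seeing the data, the 10 most abundant took 63.9%, cardiac muscle 11.5%, smooth muscle 8.43%, mesenchyme 1.95%, leukocyte 0.114%, epithelial 0.0291%, endocrine 0.00841%, pluripotent 0.0144%, Dlk1-Dio3 1.65%, Mir15 6.14%, Hox 0.187% and hypoxia 0.0979%. Without Mir126a the 10 most abundant took 62.5%, cardiac muscle 14.3%, endothelium 0.330%, smooth muscle 10.5%, mesenchyme 2.42%, erythroid 0.144%, leukocyte 0.0755%, neuronal 0.0282%, epithelial 0.0361%, endocrine 0.0105%, pluripotent 0.0178%, Dlk1-Dio3 1.76%, other imprinted 0.692%, Mir17 2.47%, Mir15 7.54%, let-7 12.5%, Mir30 9.97%, Hox 0.232% and hypoxia 0.122%.

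Depth limits genes near 10 counts, where 1 count is a large part of the value.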

Other observations

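The test in the next paragraph was written down before its result was seen.

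On the X chromosome, Mir322, Mir503 and Mir351 lie within a short stretch of the minus strand, between 53053255 and 53054349. Mir351 was 1.43-fold higher in replicate 2, while Mir322 and Mir503 were 1.01-fold and 1.06-fold higher. On chromosome 11, the neighbours Mir144 and Mir451a differed in opposite directions between the hearts. A hypothesis that genes of a shared transcription unit move alike between hearts was tested on 93 adjacent pairs on 1 strand within 10 kb, over 132 genes with 100 or more counts. The mean absolute difference of the log2 ratio was 0.276, against a median of 0.266 ± 0.0163 (SD) with permuted ratios (permutation test, 2-sided, 100000 permutations, p = 0.537). By the rule written down first, a value at or above the permuted median counts against the hypothesis, and the observed value was above it. The gap lay within the spread of the permuted values, so likeness between neighbours was not seen but is not excluded.

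If the opposite-strand counts at Mir497b are taken as Mir497, its neighbour Mir195a exceeded it by 1.46-fold in replicate 1 and 1.46-fold in replicate 2. With such counts credited, the leukocyte list, which then holds Mir142, took 0.114% of counts.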
